A study of Mus musculus with 12 samples.

How the data were processed

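Gene expression was measured on Illumina Mouse WG6V2 BeadChips in 12 samples of Lineage-negative, Kit-positive, CD45.2-positive bone marrow cells, a population enriched for haematopoietic stem and progenitor cells. Per the labels' protocols, the cells were flow sorted from chimeric mice 12 to 16 weeks after they had received fetal liver cells of embryonic day 13.5. Biotin labelling started from at most 250 ng of RNA. The 12 arrays form 4 groups of 3: wild type of experiment 1 (WT experiment 1), caspase-9 knockout (Casp9 KO), wild type of experiment 2 (WT experiment 2) and the double knockout of Bak and Bax (Bak/Bax DKO). Casp9 KO and WT experiment 1 lie on 1 beadchip, and Bak/Bax DKO and WT experiment 2 on another. The series text calls the samples independent. The labels do not say that they are separate animals, so p-values measure the spread between samples. Their number limits the precision.

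The deposited table of bead intensity holds 1 average value per probe and array for 45281 probes, on a linear scale without background subtraction or normalization, as far as the values show. The deposited detection score beside each intensity is headed as a p-value, but it rises with intensity on all 12 arrays. It was therefore read as 1 minus the detection p-value. The authors also deposited normalized log2 values. Their floor and their equal distributions fit a normexp background correction with an offset of 16 and quantile normalization over the 12 arrays, though no header names these steps. Per the labels, GenomeStudio and limma were used, with no version given. The 2 deposited normalized tables hold the same values. The genome build of the positions in the files is not given in the sources used here.

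The intensities were normalized again from the deposited table with neqc of limma 3.58.1 in R 4.3.3, with the detection p-value standing in for control probes, an offset of 16 and quantile normalization over all 12 arrays. The result differed from the deposited log2 values by at most 0.0197. Probes were kept where the detection p was under 0.05 on at least 3 of the 12 arrays, which left 18867 probes. Symbols were brought up to date through the Entrez ID for 38837 probes and through the accession for 105. The file's own symbol was used for 4669, and 1670 had a target ID alone. Each of the 11771 genes tested was represented by its probe with the highest mean. The files place the probe used on another chromosome than the reference annotation (GRCm38.p6) for 141 of these genes, so the gene named is uncertain there. Probes of immunoglobulin, MHC and other gene families can bind transcripts of related genes.

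A model of 4 group means was fitted with limma to all 12 arrays, which gave 8 residual degrees of freedom. Variances were moderated with eBayes, tests were two-sided, and p-values were adjusted over the genes by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called. The contrasts were Casp9 KO minus WT experiment 1, Bak/Bax DKO minus WT experiment 2, the difference of these 2 effects, and WT experiment 2 minus WT experiment 1. In the last, experiment and beadchip cannot be told apart from each other. The 2 knockout effects share no arrays.

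The 24 gene lists covered interferon response, apoptosis, p53 targets, cell cycle, blood lineages, stroma, cytokines, stress, mitochondria, sex-linked genes and the neighbours of the targeted genes. Of their 830 genes, 628 were measured. Each list was tested with camera (preset correlation of 0.01), with camera using an estimated correlation, and with fry, each adjusted over the lists. An adjusted p of a list below is camera's with the preset correlation unless stated. The samples, main design, lists, rule for naming genes and most alternatives were fixed before the data were examined. The rule named Casp9, Bak1 and Bax; the 10 largest rises and the 10 largest falls among called genes whose knockout and wild-type arrays did not overlap; up to 4 members of each list with the smallest p (8 for type I interferon-stimulated genes); and the 5 largest differences of each sign between the 2 effects. Some genes that the rule names are not reported here.

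Where a gene was below the detection limit on every array of a group, its fold is given as a lower bound against the lowest log2 value above background on those arrays. The model was tested on simulated data built from the fitted means and variances of the 11771 genes, with 200 changed genes per comparison. For Casp9 KO it recovered 54% of the genes changed by a log2 size of 1 and 90% of those changed by 2. For Bak/Bax DKO these shares were 80% and 84%, and for the difference of effects 38% and 92%. Casp9 KO and Bak/Bax DKO were simulated alike apart from the random draw, so the gap between their shares reflects that draw. False calls made up 5.52%, 5.26% and 4.88% of the genes called. A further set of genes with a smaller shift counted as changed there. The simulated values were independent between genes and had the same variance on every array. Neither a deviating array nor correlated genes were simulated, so these shares need not hold for the real data.

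The alternatives were the deposited normalized values, arrays centred on their medians without a quantile step, neqc for each beadchip alone, no background correction, no or a stricter detection filter, all probes or their mean per gene, only the 6 arrays of a comparison, array weights, the replicate number as a block, ordinary variances, a trended and robust prior, and each array left out in turn. A covariate for the Xist level and the authors' own filter on probes, which marks 25088 probes, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Fastq or image files were not used here.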

Results

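The data describe transcript levels in sorted haematopoietic stem and progenitor cells that lack caspase-9, the protease that starts the caspase cascade after mitochondria release cytochrome c, or that lack both Bak and Bax, the proteins that permeabilize the outer mitochondrial membrane. Each genotype was hybridized beside its own wild type, 3 arrays per group. The title of the series names cytokine signals regulated by caspase-9 as its subject. Mean bead intensity was 396.3 to 522.0 on the 6 arrays of experiment 1 and 321.5 to 459.9 on 5 arrays of experiment 2. It was 234.5 on Bak/Bax DKO replicate 2. Between 35.7% and 39.7% of the 45281 probes were above background on each array. Bak/Bax DKO replicate 2 stood apart: its values correlated with those of the other arrays at 0.856 to 0.869 across probes. Of 7562 probes bright in WT experiment 2, it showed 976 (12.9%) more than 3 log2 units lower, against at most 6 (0.0790%) on any other array.

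**Figure D1:**
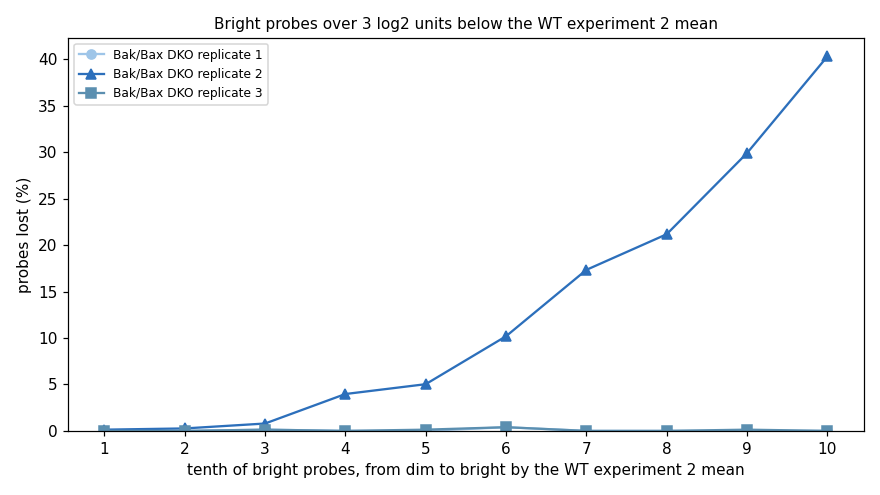
Percent of bright probes more than 3 log2 units below the WT experiment 2 mean on each Bak/Bax DKO array, in 10 classes of equal size ordered from dim to bright by the WT experiment 2 mean. On replicate 2 the share goes from 0.132% in the dimmest class to 40.3% in the brightest, while the other arrays stay near 0.

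The targeted genes followed the labels. Casp9 (probe ILMN_1217061, chromosome 4, 141371743 to 141371792 in the files) was at 8.03, 8.99 and 8.83 on the WT experiment 1 arrays and at 5.37, 5.24 and 5.48 on the Casp9 KO arrays. The group means were 8.62 ± 0.52 and 5.36 ± 0.12 on the log2 scale (SD, n = 3). The change was -3.25 (SE 0.23, limma adjusted p = 2.9e-05), and the signal stayed above background on all 3 knockout arrays. The other 3 Casp9 probes were at or near background in experiment 1 and check nothing there. In the Bak/Bax DKO experiment Casp9 was at 9.16 ± 0.12, against 9.16 ± 0.19 in its wild type.

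Bak1 (probe ILMN_2945835, chromosome 17, 27157109 to 27157158) was at 6.27, 6.59 and 6.74 on the WT experiment 2 arrays and at 4.60, 4.52 and 4.75 on the Bak/Bax DKO arrays, where it was above background on 0 of 3. It was at least 3.09-fold lower (limma adjusted p = 1.2e-04). Bax (probe ILMN_2907655, chromosome 7, 52717276 to 52717325) fell by 1.82 on the log2 scale (SE 0.17, adjusted p = 4.4e-04), from 9.34, 9.998 and 9.76 to 7.72, 8.01 and 7.91, and was above background on all 3 knockout arrays; with only the 6 arrays of the comparison its call ended (adjusted p = 0.0503). Whether these probes lie within the deleted parts is not given in the sources used here. In Casp9 KO, Bak1 changed by 0.27 (adjusted p = 0.618) and Bax by 0.04 (adjusted p = 1.00), which did not pass the test.

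The first comparison asks what the loss of caspase-9 does to these cells. Interferon-stimulated genes dominated it. The 10 largest rises were of genes known to respond to interferon. For each the knockout and wild-type arrays did not overlap, as the naming rule required. Among them were Ifit3 (log2 change 4.23 ± 0.37, SE), Isg15, a ubiquitin-like modifier (4.12 ± 0.38), Rsad2, an antiviral enzyme (4.10 ± 0.29), Usp18, which removes Isg15 from proteins (4.01 ± 0.26), and Irf7, a transcription factor of the interferon response (3.69 ± 0.30). The chemokine gene Cxcl10 went from background on all 3 wild-type arrays to 7.99 ± 0.21 (SD, n = 3), at least 8.08-fold higher, and the GTPase gene Gm4951 was at least 11.9-fold higher. Ifi27l2a rose by 3.98, the stem cell surface antigen gene Ly6a (Sca-1) by 3.77 and Oas2, which makes the second messenger 2-5A, by 3.71. With limma, 174 of 11771 genes changed in Casp9 KO, 125 up and 49 down. For all 174 the knockout and wild-type arrays did not overlap, as they did not for 2938 of all genes (24.96%), against 10% by chance.

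Of the 57 measured type I interferon-stimulated genes, 41 rose, 0 fell and 16 did not pass, and the median log2 change was 1.64. Adjusted over the list alone, 53 rose. All 57 were higher in the knockout (camera adjusted p = 1.5e-92, and adjusted p = 0.0031 with an estimated correlation). Besides those above, Oasl2 rose by 3.30, Ifi205 by 2.27, and Mx2 was at least 5.40-fold higher. Of 26 interferon-inducible GTPases and antigen presentation genes, 13 rose and 0 fell, with a median of 0.78 and 16 risen adjusted over the list alone (camera adjusted p = 2.9e-25; adjusted p = 0.0031 with an estimated correlation). The immunity-related GTPases Igtp (2.18) and Irgm2 (2.08), Tgtp1 (1.95) and the guanylate-binding protein gene Gbp5 were among them, Gbp5 at least 2.03-fold higher. The calls on all genes named so far for Casp9 KO held with each of the 12 arrays left out in turn.

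**Figure D2:**
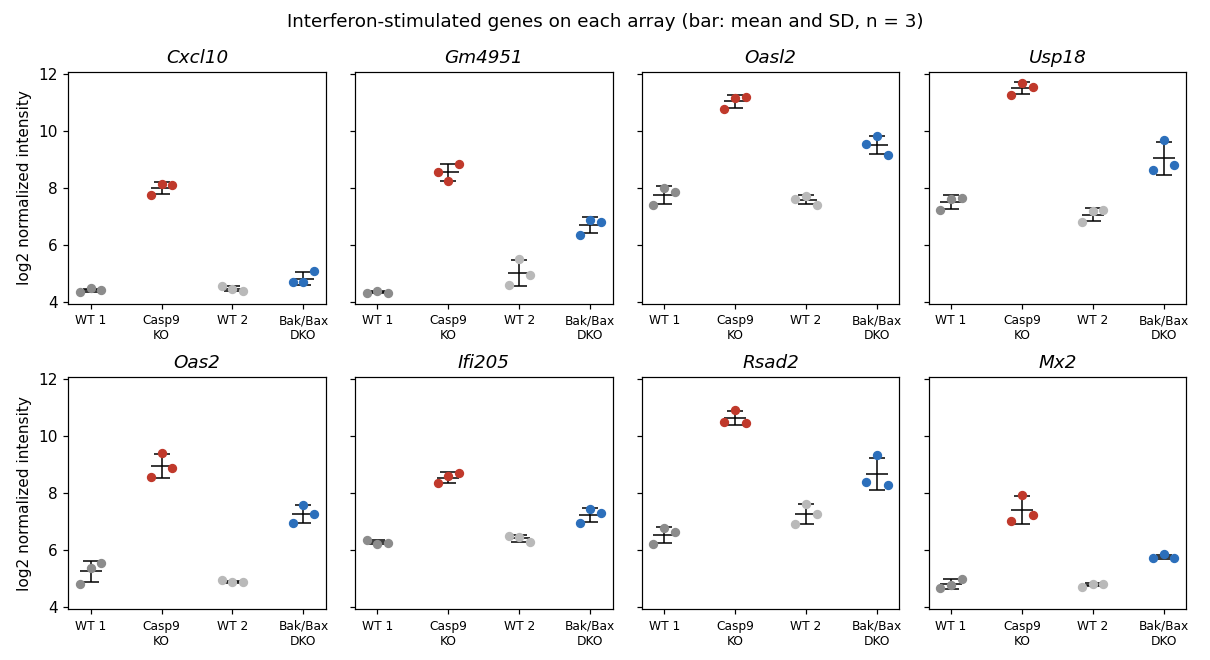
Log2 normalized intensity of 8 type I interferon-stimulated genes on each of the 12 arrays, with the mean and SD of each group (n = 3). The Casp9 KO arrays lie above all WT experiment 1 arrays for each gene, and the Bak/Bax DKO arrays lie above all WT experiment 2 arrays but at lower levels than in Casp9 KO.

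Measured genes for interferons, their receptors and the kinases Jak1 and Tyk2 did not show this. The unmeasured ones, interferon genes among them, were not tested. Of the 25 in the list, 10 were measured. With limma 0 of them were called and 1 had an unadjusted p under 0.05, Ifnar2, a type I interferon receptor chain (0.45, adjusted p = 0.420); camera gave adjusted p = 0.310 and fry 0.138. Of 26 cytosolic nucleic acid sensing genes, 5 of which are also in the interferon-stimulated list, 1 rose, the DNA sensor family member Ifi203 (2.04), and 4 rose adjusted over the list alone. That list's median was 0.25 (camera adjusted p = 2.8e-05; adjusted p = 0.114 with an estimated correlation). Without Bak/Bax DKO replicate 2, 8 of the 26 rose and the adjusted p with an estimated correlation was 0.0301. Among 34 cytokine, chemokine and feedback genes, 3 rose, 0 fell and 5 rose adjusted over the list alone: Cxcl10, Cxcl9 (at least 3.12-fold higher) and Ccl4 (1.63), while Ccl5 (1.70, adjusted p = 0.0519) passed only without Bak/Bax DKO replicate 2 (adjusted p = 2.7e-04) or 3 (0.0266) among the arrays left out. The median was 0.40 (adjusted p = 2.6e-10; adjusted p = 0.062 with an estimated correlation). Without that same array 5 rose and the latter value was 0.0369. The Cxcl9 call was lost without any of the 3 WT experiment 1 arrays, and the Ccl4 call without 5 of the 12 arrays taken singly: all WT experiment 1 arrays and Casp9 KO replicates 2 and 3.

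Lineage markers also shifted in Casp9 KO. Erythroid genes were lower: 43 of 43 measured members lay below wild type, with a median of -0.62 (camera adjusted p = 2.5e-13; adjusted p = 0.045 with an estimated correlation). Of these, 3 fell and 18 fell adjusted over the list alone. Without Bak/Bax DKO replicate 2, 22 of 42 fell, and the adjusted p with an estimated correlation was 0.0540. The spectrin-binding gene Add2 fell by 1.07, the nuclear protein gene Hemgn by 0.86 and the repressor gene Gfi1b by 0.89. Megakaryocyte and platelet genes had a median of -0.33; 1 of 24 fell (Mmrn1, by 1.17) and 4 adjusted over the list alone (adjusted p = 1.7e-04; adjusted p = 0.062 with an estimated correlation). With that array left out, 5 of 23 fell and the latter value was 0.0369. In the other direction, monocyte, macrophage and dendritic cell genes had a median of 0.55, with 2 of 34 risen, Mpeg1, which makes a pore-forming protein (1.29), and H2-Aa (1.48), and 10 risen adjusted over the list alone (adjusted p = 9.0e-13; adjusted p = 0.035 with an estimated correlation). Without that array 12 of the 34 rose, as did 6 of 17 mast cell and 4 of 31 neutrophil genes. Mast cell, basophil and eosinophil genes had a median of 0.61, with 3 of 17 risen, the basophil protease gene Mcpt8 (1.24), Fcer1a (1.76) and Il4 (1.36), and 5 adjusted over the list alone (adjusted p = 2.8e-05; adjusted p = 0.011 with an estimated correlation). Of 31 neutrophil lineage genes 2 rose, Clec5a (1.02) and Cxcr2 (at least 1.36-fold higher), and 2 adjusted over the list alone (median 0.47, adjusted p = 5.5e-07; adjusted p = 0.114 with an estimated correlation). Of the calls on genes of these lineages, that on Mcpt8 held with each array left out, and each of the others was lost for 5 to 9 of the 12 arrays.

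The 36 stem and multipotent progenitor markers went both ways. Ly6a and the homeobox gene Hoxb5 (1.19) rose, and the endothelial receptor gene Robo4 and Gfi1b fell by 1.27 and 0.89. The calls on Robo4 and Hoxb5 were lost without 3 and 5 of the 12 arrays taken singly, and that on Dntt in the B lymphoid list without 8. Adjusted over the list alone, 3 rose and 7 fell. Their median was -0.06 and their mean 0.01, and camera gave adjusted p = 0.475, on the lower side. Of 20 B lymphoid genes 1 fell, Dntt, the polymerase that adds nucleotides at V(D)J joints, by 1.23, and 2 adjusted over the list alone (median -0.29, adjusted p = 0.017; adjusted p = 0.331 with an estimated correlation). T and NK lymphoid genes had 0 of 12 calls with limma, 3 members at an unadjusted p under 0.05, 3 rises adjusted over the list alone and a median of 0.25 (adjusted p = 7.9e-04; adjusted p = 0.114 with an estimated correlation; fry 0.034). Without a detection filter the T and NK median was 0.011 and the list's call was lost (adjusted p = 0.0509). The sialomucin gene Emcn, in the endothelium and stroma list, was at least 2.97-fold lower, the 1 call among 15 members, with 3 falls adjusted over the list alone (median -0.23, adjusted p = 0.036; adjusted p = 0.194 with an estimated correlation). When Bak/Bax DKO replicate 2 was left out, 3 stem and progenitor markers rose and 8 fell, 2 B lymphoid and 3 endothelium and stroma genes fell, and 4 T and NK genes rose. Leaving out WT experiment 1 replicate 3 ended the calls on the B lymphoid list (adjusted p = 0.153) and the endothelium list (adjusted p = 0.0672). The former was also lost without Casp9 KO replicate 1 (adjusted p = 0.0825) and the latter without Bak/Bax DKO replicate 1 (adjusted p = 0.0554). Without a detection filter the endothelium median was 0.023 and the call was lost (adjusted p = 0.879). That call was also lost with no background correction, with probes averaged and with array weights.

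The other largest falls in Casp9 KO were Spon2 (-2.20), Sh3tc2 (-1.91), Denn2b (-1.61), Tceal6 (-1.53), the membrane protein gene Emp1 (-1.52), the angiotensin receptor gene Agtr1a (-1.44), Prss50 (-1.39) and Lrig1, a negative regulator of ErbB receptors, at least 2.10-fold lower. The calls on Spon2, Agtr1a and Prss50 were lost without 8, 6 and 3 of the 12 arrays taken singly, and those on Ccnd2 and Klf6 without 4 and 2. Of 29 genes of the intrinsic apoptosis machinery, Casp9 alone was called; Bcl2l11, which encodes Bim, was at -0.71 (adjusted p = 0.0805), and its fall passed without Bak/Bax DKO replicate 1 (adjusted p = 0.0241) or 2 (adjusted p = 0.0081). Without the latter 1 gene of that list rose and 2 fell. That list's median was -0.09 (adjusted p = 0.402). Ccnd2 (1.24) was the 1 call among 40 cell cycle genes (median -0.10, adjusted p = 0.230), Klf6 (1.58) that among 32 stress and early response genes (median 0.21, adjusted p = 0.0648), and Ccl4 that among 21 NF-kappaB targets (median 0.24, adjusted p = 8.5e-04; adjusted p = 0.205 with an estimated correlation). When Bak/Bax DKO replicate 2 was left out, 4 NF-kappaB targets rose and 1 fell, and 3 stress genes rose and 1 fell. Among 23 p53 targets 0 were called and 4 had an unadjusted p under 0.05, Cdkn1a with the smallest (1.08, adjusted p = 0.110; list adjusted p = 0.310, fry 0.630). With that array left out, Cdkn1a (1.09, adjusted p = 0.0049) and Fas (adjusted p = 0.012) rose. With limma, 0 genes were called among 32 of the mitochondrial respiratory chain (adjusted p = 0.767, fry 0.630) and 30 of mitochondrial biogenesis and quality control (adjusted p = 0.0540, fry 0.453), with 0 and 1 at an unadjusted p under 0.05. The biogenesis list passed camera without Casp9 KO replicate 1 (adjusted p = 0.0204), WT experiment 1 replicate 3 (0.0449) or Bak/Bax DKO replicates 1, 2 or 3 (0.0367, 0.0457 and 0.0467), and the stress list without Casp9 KO replicate 1 (0.0446). Of 10 neighbours of Casp9 0 were called (1 at an unadjusted p under 0.05; adjusted p = 0.905, fry 0.852). Their member Necap2 was at -0.83 (adjusted p = 0.152), but at -4.14 (adjusted p = 1.4e-07) without Bak/Bax DKO replicate 2, where another of its probes was the brightest. Without Casp9 KO replicates 1, 2 and 3, Necap2 was at -4.22, -4.00 and -4.16, also past the test. The list's mean was -0.04, and -0.41 without Bak/Bax DKO replicate 2. There were 0 calls among 21 neighbours of Bak1 and Bax (3 at an unadjusted p under 0.05; adjusted p = 0.905, fry 0.752) or 5 sex-linked genes (0 at an unadjusted p under 0.05; adjusted p = 0.264, fry 0.433).

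The count of 174 genes was 667 without Bak/Bax DKO replicate 2, all 174 among them, and 87, 93, 93 and 89 without WT experiment 1 replicates 1, 2 and 3 and Casp9 KO replicate 3. It was 936 with array weights, 589 with only the 6 arrays of the comparison and 107 with the Xist level as a covariate. Of the calls 71.8% were rises here, 85.4% with median-centred arrays, 56.2% without Bak/Bax DKO replicate 2, 54.7% with array weights and 54.7% with only the 6 arrays.

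**Figure D3:**
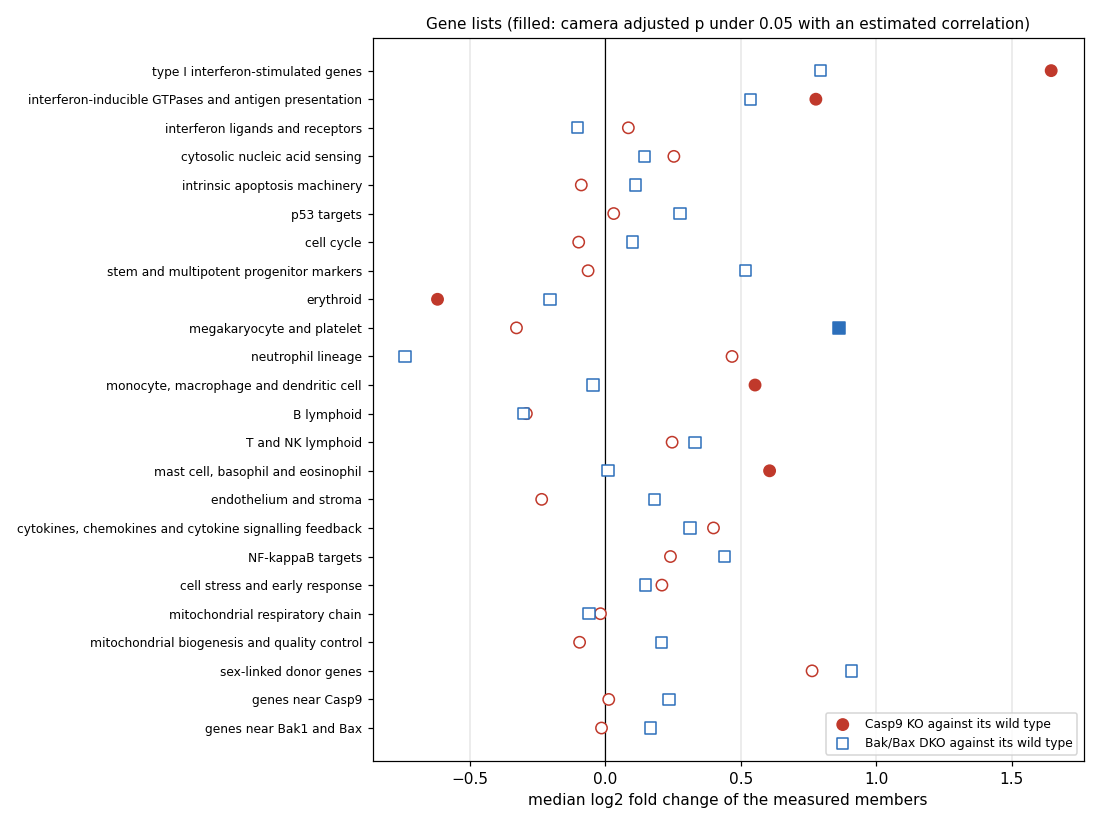
Median log2 fold change of the measured members of each of the 24 gene lists in Casp9 KO (circles) and Bak/Bax DKO (squares), each against its own wild type; filled symbols mark lists past camera with an estimated correlation. Interferon-stimulated genes have the highest median in Casp9 KO (1.64), and neutrophil and megakaryocyte lists lie on opposite sides of 0 in the 2 knockouts.

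The second comparison asks what changes when mitochondrial permeabilization itself is blocked. Immunoglobulin light chain and MHC class II transcripts were among the largest rises in Bak/Bax DKO: Igl rose by 4.69 ± 0.68 (SE), Igk by 3.23 ± 0.44, the invariant chain gene Cd74 by 3.05 ± 0.42 and H2-Eb1 by 2.83 ± 0.35. Megakaryocyte, stem cell and interferon-stimulated genes were higher as lists, and neutrophil genes were lower, with 2 of 31 falling. Of these lists, that of megakaryocyte genes passed with an estimated correlation, and those of stem cell (adjusted p = 0.102), interferon-stimulated (0.162) and neutrophil genes (0.102) did not. Vpreb1 and Igll1, which encode the surrogate light chain of B cell precursors, fell by 2.11 and 2.07. With limma, 255 of 11771 genes changed in Bak/Bax DKO, 198 up and 57 down. For all 255 the arrays did not overlap, as for 2187 of all genes (18.6%), against 10% by chance. The light chain probes Igkv4-55 (3.33), Igkv6-14 (3.19) and Igkv4-53 (3.19) also rose. Their calls were lost without 4, 2 and 3 of the 12 arrays taken singly. Outside the naming rule, the heavy chain genes Ighm (1.17) and Ighv10-3 (1.57) were called as risen too. Other Ighm probes ranged from -0.04 to 3.69.

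Of the 57 type I interferon-stimulated genes, 22 rose, 0 fell and 35 did not pass, with a median of 0.79 and 34 risen adjusted over the list alone (camera adjusted p = 4.7e-18). The list did not pass with an estimated correlation (adjusted p = 0.162), and fry gave 0.0018. Oas2 rose by 2.39, Usp18 by 1.98, Oasl2 by 1.93, Oas1g by 1.91 and Gm4951 by 1.68. Smaller rises were those of Parp14 (1.15), Epsti1 (1.02) and Irf9, the DNA-binding part of the complex ISGF3 (0.97). Other probes of Usp18 were at 2.02 and 2.07, of Oasl2 at 1.29, and of Oas1g at 1.70 and -0.03. Those of Parp14, Epsti1 and Irf9 were at -0.26, 0.42 and 0.48. Of 26 GTPase and antigen presentation genes 6 rose, among them H2-Q7 (1.21), Irgm2 (1.14), Gbp2 (1.12) and Cd274, which encodes PD-L1 (1.20), and 14 rose adjusted over the list alone (median 0.54, adjusted p = 1.9e-04; adjusted p = 0.171 with an estimated correlation). Another probe of Gbp2 was at 0.097, and those of H2-Q7 were at 0.68, 1.19 and -1.27. The call on Irgm2 was lost without WT experiment 2 replicate 1 or 3. That on Cd274 was lost without any WT experiment 2 array or WT experiment 1 replicate 2. Interferon ligand and receptor genes had 0 of 10 calls and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0809, fry 0.0877), and the 26 nucleic acid sensing genes had 0 and 4 (adjusted p = 0.634, fry 0.224).

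Megakaryocyte and platelet genes were higher as a list in Bak/Bax DKO. Mmrn1, which encodes a platelet granule protein, rose by 1.81 ± 0.24 (SE) and Treml1, which encodes a platelet receptor, by 1.62 ± 0.25. Of 24 members 9 rose, 0 fell, and 15 rose adjusted over the list alone; the median was 0.86 (camera adjusted p = 2.8e-09; adjusted p = 0.039 with an estimated correlation). Of 36 stem and multipotent progenitor markers 12 rose and 0 fell, among them Ndn (2.51) and Vldlr (1.19), and 14 rose adjusted over the list alone (median 0.52, adjusted p = 1.2e-08; adjusted p = 0.102 with an estimated correlation). Without Bak/Bax DKO replicate 2 that estimated-correlation value was 0.0023, and 12 of 23 megakaryocyte genes rose. That same array's removal gave 5 falls and 1 rise among B lymphoid genes, 5 falls among mast cell genes, and 6 rises and 5 falls among monocyte, macrophage and dendritic cell genes.

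Neutrophil lineage genes had a median of -0.74, with 27 of 31 members not higher than wild type in mean. Fcnb, which encodes ficolin B, fell by 2.04 and Wfdc21 by 1.18; 8 fell adjusted over the list alone and 14 over all genes without Bak/Bax DKO replicate 2 (camera adjusted p = 7.6e-12; adjusted p = 0.102 with an estimated correlation). Of 20 B lymphoid genes Vpreb1, Igll1 and Cd79a (at least 1.34-fold lower) fell, and adjusted over the list alone 2 rose and 5 fell (median -0.30, adjusted p = 4.3e-05; adjusted p = 0.171 with an estimated correlation). Monocyte, macrophage and dendritic cell genes split, 6 up and 2 down of 34, with H2-Eb1, Cd74 and the complement gene C1qb (at least 2.85-fold higher) against Klf4 (-1.33), and 7 up and 7 down adjusted over the list alone (median -0.04, mean 0.01, adjusted p = 0.140). Among mast cell genes Cma1, a chymase gene (at least 2.27-fold higher), Cpa3 (0.90) and Alox5 (0.76) rose, 3 of 17 (median 0.01, mean -0.47, adjusted p = 0.894). Adjusted over the list alone, 4 of these mast cell genes rose and 3 fell; fry, whose direction was up, gave 0.0877. Their mean change was -1.19 on Bak/Bax DKO replicate 2 against -0.19 and -0.017 on replicates 1 and 3. With that array left out the mean was -0.11, the median 0.081 and the direction of fry down (adjusted p = 0.763). The calls on Wfdc21 and Cpa3 were lost without 8 of the 12 arrays taken singly, on Cd79a without 4, on Alox5 without 3 and on Klf4 without 2.

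Among cytokine and feedback genes 5 of 34 rose, including Ltb, which encodes lymphotoxin beta (2.26), Cish (1.42), Il1b (1.36) and Socs3 (1.17), and 7 rose and 2 fell adjusted over the list alone (median 0.31, adjusted p = 0.016; adjusted p = 0.577 with an estimated correlation). The list's call was lost without WT experiment 2 replicate 3 (adjusted p = 0.0502) or Bak/Bax DKO replicate 3 (adjusted p = 0.102). Its median was 0.16 without Bak/Bax DKO replicate 2, whose mean change was 0.65 against 0.19 and 0.37 on replicates 1 and 3. Of 21 NF-kappaB targets 2 rose, Il1b and Ccl4 (1.29), and 4 adjusted over the list alone (median 0.44, adjusted p = 0.0017; adjusted p = 0.312 with an estimated correlation). Of 12 T and NK genes, the adaptor gene Lat rose (0.98) and Nkg7 fell by 1.45 (median 0.33, adjusted p = 0.494; 3 up and 2 down adjusted over the list alone). Vwf (1.10) was the 1 call among 15 endothelium and stroma genes (median 0.18, adjusted p = 0.618, with 4 up and 1 down adjusted over the list alone). Another Vwf probe was at -0.02, and Vwf is also in the megakaryocyte and platelet list. Of these calls, that on Zfpm1 was lost without 9 of the 12 arrays taken singly, on Ccl4 without 8, on Lat without 5, on Il1b and Nkg7 without 4, and on Socs3 and Vwf without 3. Erythroid genes had a median of -0.20 with 1 call of 43, a rise of Zfpm1 (0.66), and adjusted p = 0.024, which was 0.616 with an estimated correlation. That list's call was lost without Bak/Bax DKO replicate 1 (median -0.017, adjusted p = 0.0782) or WT experiment 2 replicate 3 (median -0.12, adjusted p = 0.0502). It was also lost with the Xist covariate (median -0.054, adjusted p = 0.123) and without a detection filter (median -0.059, adjusted p = 0.084).

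Among 23 p53 targets Zmat3 rose (1.02) and Dram1 fell by 1.07, with 4 up and 1 down adjusted over the list alone and a median of 0.28 (adjusted p = 0.136) that was -0.01 with median-centred arrays. Without 3 and 2 of the 12 arrays taken singly, the calls on Zmat3 and Dram1 were lost. Cell cycle genes had 0 of 40 calls, 4 at an unadjusted p under 0.05 and a median of 0.10 that was -0.26 with median-centred arrays (mean -0.18, adjusted p = 0.733, fry 0.525). Of 29 apoptosis genes Bak1 and Bax fell and the others did not pass, among them Bbc3, which encodes Puma (0.90, adjusted p = 0.142; list median 0.11, mean -0.07, adjusted p = 0.689). With Bak/Bax DKO replicate 2 left out, Bbc3 was at 0.55 and the list's median at -0.046. There fry gave 8.0e-04 (down), but the list holds Bak1 and Bax themselves, so this does not show a fall of its other members. The same removal turned the medians of cell cycle and nucleic acid sensing genes to -0.039 and -0.021. Stress genes had 0 of 32 calls and 6 at an unadjusted p under 0.05 (median 0.15, mean -0.19, adjusted p = 0.894, fry 0.0880), and sex-linked genes 0 of 5 and 0 (adjusted p = 0.731, fry 0.349). The negative mean of the stress genes came from Bak/Bax DKO replicate 2 (-0.93, against 0.17 and 0.19 on replicates 1 and 3); with it left out their mean was 0.18 and their median 0.088. Respiratory chain genes had 0 of 32 calls and 1 at an unadjusted p under 0.05, a median of -0.06 and a mean of -0.74 (adjusted p = 0.015; adjusted p = 0.266 with an estimated correlation; fry 0.205). Without Bak/Bax DKO replicate 2 their mean was -0.16, and 1 member, Cox7b, passed limma as lower (-0.91, adjusted p = 0.0086). Without replicate 1 their median was 0.01, and without WT experiment 2 replicate 3 the list's call was lost (adjusted p = 0.0502). Mitochondrial biogenesis genes had 0 of 30 calls and 1 at an unadjusted p under 0.05 (median 0.21, adjusted p = 0.216, fry 0.263). Their median was 0.042 without Bak/Bax DKO replicate 2; the mean change was 0.39 on that array and -0.042 and 0.032 on replicates 1 and 3.

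The largest falls in Bak/Bax DKO were those of Htatip2 (-5.13 ± 0.15, SE; -5.17 with an overlapping probe), Mtm1 (at least 16.1-fold lower), Ndufb10 (-4.20 ± 0.25), Ctu1 (at least 8.49-fold lower) and Zfp945 (at least 6.72-fold lower). The files place the Mtm1 probe on another chromosome than the reference does, so that name is uncertain. Ndufb10 is read by 2 probes, and with the other it was at 1.05 without WT experiment 1 replicate 1; the Ndufb10 call reversed in this way without 7 of the 12 arrays taken singly. Dkkl1 (-2.26), Rab44 (-2.19) and Tedc2 (at least 2.85-fold lower) fell as well. Snrpn (at least 10.5-fold higher) and Ndn (2.51) are imprinted genes of the same chromosome region; the Snrpn value was -0.25, -0.10 and -0.13 without Bak/Bax DKO replicates 1, 2 and 3, where another of its probes was the brightest, and a further probe was at 2.86 with all arrays used. By the positions in the files, Ndufb10, Zfp945, Rab44, Tedc2, H2-Eb1, H2-Q7 and Ltb lie within 20 Mb of Bak1, and Htatip2, Ctu1, Dkkl1, Nkg7, Snrpn and Ndn within 20 Mb of Bax. In these windows 47 of 557 genes (8.44%) were called, 25 up and 22 down, against 206 of 11185 (1.84%) elsewhere (two-sided Fisher's exact p = 3.7e-16). The same windows held 8 of 557 calls in Casp9 KO (exact p = 1.00). Between the wild types they held 53 of 557 (9.52%), against 7.20% elsewhere (exact p = 0.0450). Within 10 Mb the share was 10.2% in Bak/Bax DKO (exact p = 8.2e-18) and 8.77% between the wild types (exact p = 0.252). Of the 21 nearest neighbours of Bak1 and Bax fixed as a list, Bcat2 (1.11) and Ftl1 (0.60) were called and 3 rose adjusted over the list alone (median 0.17, adjusted p = 0.374). Without Bak/Bax DKO replicate 2 the median was -0.048, with 1 rise. The Bcat2 and Ftl1 calls were lost without 2 and 7 of the 12 arrays taken singly. The files place the Ftl1 probe on another chromosome than the reference does, and Ftl1 was at -0.68 with its probes averaged and at -0.07 without Bak/Bax DKO replicate 2. The 10 neighbours of Casp9 had 0 calls, 1 at an unadjusted p under 0.05 (adjusted p = 0.216, fry 0.168).

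**Figure D4:**
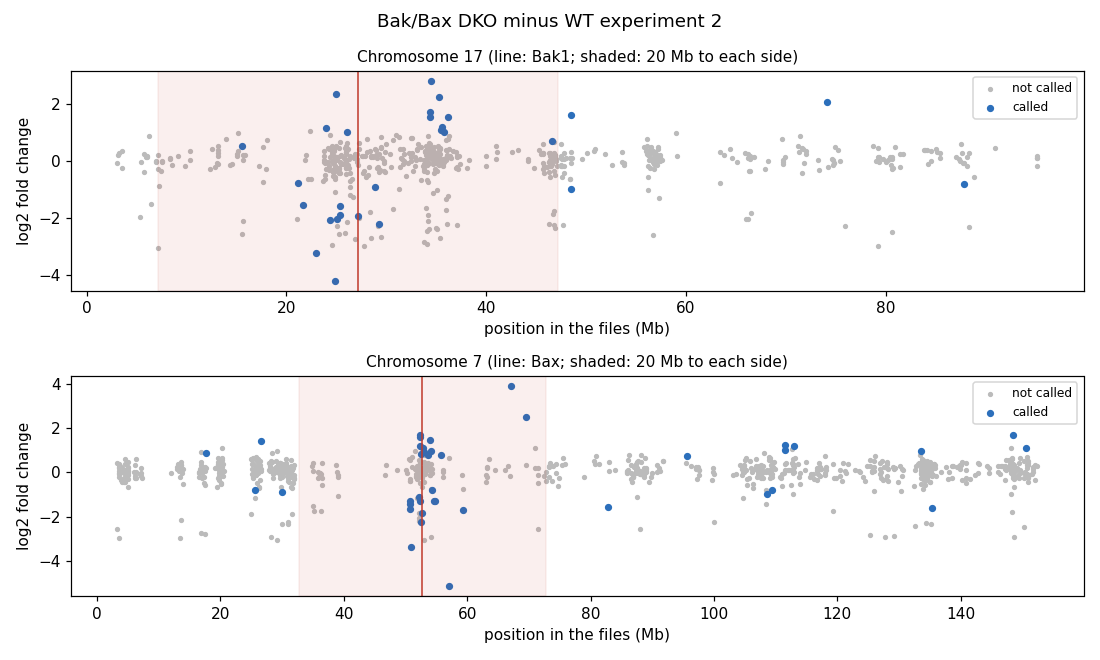
Log2 fold change of each gene tested in Bak/Bax DKO against WT experiment 2 along chromosomes 17 and 7, by the probe positions in the files; called genes are blue and the shaded windows reach 20 Mb to each side of Bak1 and Bax. Called genes of both directions lie close to the targeted genes.

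The count of 255 genes was 468 without Bak/Bax DKO replicate 2 (242 of the 255 among them), 404 without replicate 1, and 113, 110 and 97 without WT experiment 2 replicates 1, 2 and 3; it was 21 with only the 6 arrays of the comparison, 571 with array weights and 147 with the Xist covariate. The median of all genes was 0.11 here and -0.14 with median-centred arrays, where 93 genes were called and 45.2% of them were rises, against 77.6%. Rises made up 55.1% of the calls without Bak/Bax DKO replicate 2, 86.6% without replicate 1, 55.9% with array weights and 47.6% with only the 6 arrays. Of the 59 called genes named, 28 lost their call with median-centred arrays and 47 with only the 6 arrays of the comparison. In the main fit, and in those with 1 array left out, the variance is shared with the other groups. It can therefore understate the spread within this comparison, which holds Bak/Bax DKO replicate 2.

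The difference of the 2 effects was tested directly. The median rise of the interferon-stimulated genes was larger in Casp9 KO. For 15 of 57 the difference passed, all higher in Casp9 KO, and for 28 adjusted over the list alone. The median difference was 0.93 (camera adjusted p = 4.4e-27; adjusted p = 0.076 with an estimated correlation). Without Bak/Bax DKO replicate 2, 33 of 57 passed and the adjusted p with an estimated correlation was 0.0356. The GTPase and antigen presentation genes differed by a median of 0.52, with 2 of 26 passing and 7 adjusted over the list alone (adjusted p = 7.3e-07; adjusted p = 0.076 with an estimated correlation). Megakaryocyte and platelet genes differed the other way by -1.08, with 9 of 24 passing, all lower in Casp9 KO, and 16 adjusted over the list alone (adjusted p = 9.9e-10; adjusted p = 0.034 with an estimated correlation). Neutrophil lineage genes differed by 1.42, with 2 of 31 passing and 17 adjusted over the list alone (adjusted p = 5.4e-15; adjusted p = 0.076 with an estimated correlation). With Bak/Bax DKO replicate 2 left out, 7 GTPase and antigen presentation, 14 of 23 megakaryocyte and 19 neutrophil genes passed.

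Stem and multipotent progenitor markers differed by -0.48, with 9 of 36 passing as lower in Casp9 KO, and 3 higher and 14 lower adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.176 with an estimated correlation, and 0.0150 without Bak/Bax DKO replicate 2). Monocyte, macrophage and dendritic cell genes differed by 0.53 (5 of 34; adjusted p = 3.2e-06; adjusted p = 0.148 with an estimated correlation), erythroid genes by -0.63 (2 of 43; adjusted p = 0.0094; adjusted p = 0.476 with an estimated correlation) and mast cell, basophil and eosinophil genes by 0.99 (1 of 17; adjusted p = 0.021; adjusted p = 0.102 with an estimated correlation). Nucleic acid sensing genes differed by 0.21 (1 of 26; adjusted p = 0.019; adjusted p = 0.449 with an estimated correlation), and mitochondrial biogenesis genes by -0.29 with 0 of 30 passing and 3 at an unadjusted p under 0.05 (adjusted p = 0.046; adjusted p = 0.661 with an estimated correlation; fry 0.277). The last was 0.06 with median-centred arrays, and its call was lost without any of 6 arrays. Without Bak/Bax DKO replicate 2, 1 of these, it was -0.14 (adjusted p = 0.347), and without each of the others it was -0.26 to -0.31. The erythroid call was lost without Casp9 KO replicate 3 (adjusted p = 0.0535) and the mast cell call without WT experiment 2 replicate 2 (adjusted p = 0.0542). Without a detection filter the mast cell difference was 0.16 and its call was lost as well (adjusted p = 0.061). With Bak/Bax DKO replicate 2 left out, 10 monocyte, macrophage and dendritic cell genes passed as higher and 1 as lower, and 6 erythroid, 6 mast cell and 2 nucleic acid sensing genes passed. The other 14 lists did not pass camera. With single arrays left out, the cytokine list passed without Casp9 KO replicate 1 (adjusted p = 0.0125), Bak/Bax DKO replicate 2 (0.0289) or WT experiment 2 replicate 3 (0.0357). The B lymphoid list did so without WT experiment 1 replicate 3 (0.0325) or WT experiment 2 replicate 3 (0.0170), and the interferon ligand list without the latter (0.0334).

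With limma, the change of 245 of 11771 genes differed between the knockouts, 105 higher and 140 lower in Casp9 KO. By the fitted values, the named genes on the higher side were Htatip2 (5.11), Ndufb10 (4.14), Mtm1, Zfp945 and Ctu1, which fell in Bak/Bax DKO, and on the lower side Igl (-4.42), Igkv6-14 (-3.82), Igkv4-53 (-3.78), Casp9 (-3.25) and Snrpn. Since Mtm1, Zfp945, Ctu1 and Snrpn were below detection on every array of a group, their fitted values are neither measured sizes nor bounds and are left out here. The calls on Ndufb10 and Snrpn reversed without 7 and 3 of the 12 arrays taken singly. The light chain calls were lost without 9, 7 and 9 of the 12 arrays taken singly. The count was 825 without Bak/Bax DKO replicate 2; 97 and 96 without WT experiment 1 replicates 1 and 2, and 49 higher with 55 lower without replicate 3; 129, 109 and 107 without WT experiment 2 replicates 1, 2 and 3; and 142 and 96 without Casp9 KO replicates 1 and 3. It was 930 with array weights, 143 with ordinary variances, 163 with the Xist covariate, and 162 with median-centred arrays, where 80.2% were higher in Casp9 KO against 42.9% here. That share was 55.5% without Bak/Bax DKO replicate 2 (458 higher, 367 lower), 24.7% without replicate 1 (82 higher, 250 lower), 36.5% without replicate 3 and 53.4% with array weights. The median of all genes moved from -0.12 to 0.15 with that centring.

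The genes that rose in both knockouts overlapped. Of 125 and 198 rises 41 were shared, against 2.10 for independent lists (two-sided Fisher's exact p = 1.3e-42), and 21 of the 41 are in the type I interferon-stimulated list. The exact tests treat genes as independent. Both comparisons also use the same variance per gene, which favours shared calls, so these p-values are descriptive only. For Oas2, Usp18 and Oasl2 the changes in Casp9 KO were 3.71, 4.01 and 3.30, against 2.39, 1.98 and 1.93 in Bak/Bax DKO. Ly6a rose in both as well. No gene fell in both (0, against 0.237 for independent lists). In opposite directions, 3 genes fell in Casp9 KO and rose in Bak/Bax DKO (0.824 for independent lists, exact p = 0.0491), and 2 rose in Casp9 KO and fell in Bak/Bax DKO (0.605, exact p = 0.123). Over all 11771 genes, which are not independent replicates, the 2 effects had a Pearson correlation of 0.0088 and a Spearman correlation of -0.124.

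**Figure D5:**
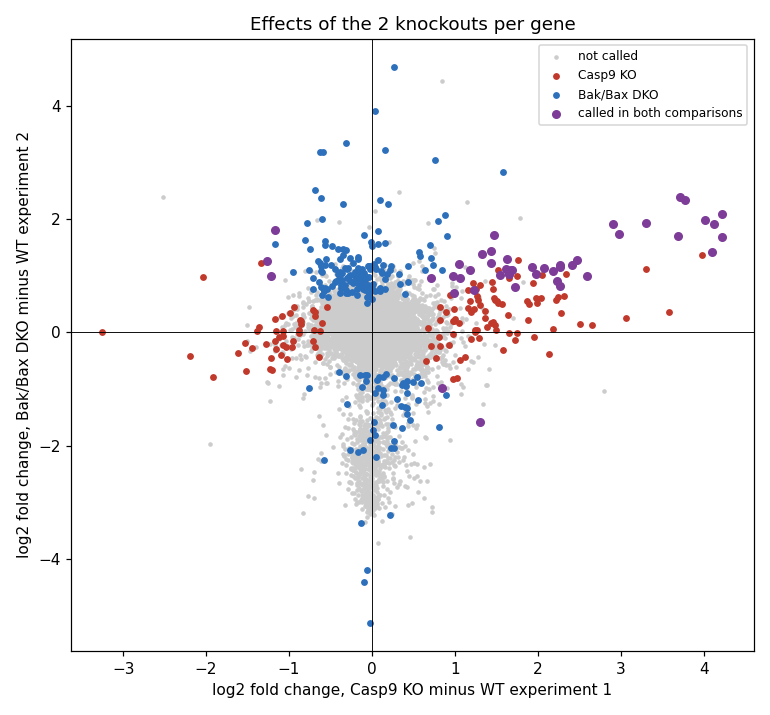
Log2 fold change in Bak/Bax DKO against that in Casp9 KO for each of the 11771 genes tested, coloured by the comparison in which the gene was called. The 41 genes that rose in both lie at the upper right, with larger changes in Casp9 KO for most, and uncalled genes with low values in Bak/Bax DKO form a vertical band.

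The 2 wild types, which differ in experiment and beadchip at once, differed in 861 genes, 531 higher and 330 lower in WT experiment 2. This count was 407, 360 and 326 without WT experiment 1 replicates 1, 2 and 3, 413, 380 and 421 without WT experiment 2 replicates 1, 2 and 3, and 2346 without Bak/Bax DKO replicate 2. It was 351 with median-centred arrays (80.9% higher, against 61.7%), 1399 with all probes, 3207 with array weights and 2727 with only these 6 arrays. The share of higher genes was 53.5% without Bak/Bax DKO replicate 2, 50.4% with array weights and 50.8% with only these 6 arrays.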

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

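The tests of the loss of Bak and Bax, of placement near the targeted genes, of sequence variants under probes, of admixed cells and of losses expected from brightness were chosen after the results they concern had been seen, and the Xist covariate was added after the main results had been seen but before its own.

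The change of 245 genes differed between the knockouts by the direct test of the difference. Of 100 splits drawn from the 200 within the experiments, 1, the real one, gave as many genes. The highest of the others gave 41. The real grouping of the arrays thus stood out among the splits drawn. Splits that mix knockout and wild-type arrays move any knockout effect into the spread, which lowers their counts. This test therefore cannot tell whether the effects of the knockouts differ from each other beyond chance. For each of the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave as many genes: 174 in Casp9 KO, 255 in Bak/Bax DKO and 861 between the wild types, with a highest other count of 0.

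The named genes that differed were Htatip2 (5.11), Mtm1 (4.31), Ndufb10 (4.14), Zfp945 (3.44) and Ctu1 (3.23), higher in Casp9 KO relative to Bak/Bax DKO, and Igl (-4.42), Snrpn (-3.87), Igkv6-14 (-3.82), Igkv4-53 (-3.78) and Casp9 (-3.25), lower. These are fitted values; Mtm1, Zfp945, Ctu1 and Snrpn were below detection on every array of a group, so theirs are neither measured sizes nor bounds. Of these 10 calls 5 held with every array left out. By the median of their members, lists with a difference were neutrophil lineage (1.42), mast cell, basophil and eosinophil (0.99), type I interferon-stimulated (0.93), monocyte, macrophage and dendritic cell (0.53), interferon-inducible GTPases and antigen presentation (0.52) and cytosolic nucleic acid sensing genes (0.21) on the higher side. On the lower side were megakaryocyte and platelet (-1.08), erythroid (-0.63), stem and multipotent progenitor (-0.48) and mitochondrial biogenesis genes (-0.29). Of these 10 lists, that of megakaryocyte and platelet genes passed with an estimated correlation (adjusted p = 0.034).

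Bak/Bax DKO replicate 2 lacked signal at 976 bright probes, of which 777 (79.6%) were not above background there. The lowest intensity on that array was 0, against 68.9 to 101.3 on the other arrays. Of the lost probes 0.410% were also lost on another Bak/Bax DKO array, which argues against the loss of Bak and Bax as the cause. The share lost was 41 times higher in the brightest than in the dimmest of 3 equal classes of bright probes, which argues against a low amount of labelled RNA. Of 902 bright sister probes of the same genes 23.9% (216) were lost too, where brightness alone gives 197. This is consistent with a fault of single bead types on that array that grows with brightness; what such a fault would be stays open.

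Called genes in Bak/Bax DKO lay near Bak1 and Bax more often than elsewhere (two-sided Fisher's exact p = 3.7e-16), which argues against chance placement. Between the wild types this p was 0.0450 for the 20 Mb windows and 0.252 for 10 Mb. Of the other probes of the called genes there, 54.8% (17 of 31) moved with the probe used, against 65.8% (73 of 111) for called genes elsewhere (two-sided Fisher's exact p = 0.296). These probes came from 21 and 69 genes, and the test counts probes of the same gene as independent, so its p is descriptive only. The 54.8% lies between the values set for the alternatives. Sequence variants under single probes therefore cannot be told apart from changed transcript levels for these genes as a set. Single genes differed. Other probes of H2-Ab1 (1.85, 1.60 and 1.41) and Nosip (0.93 and 1.12) moved with the probes used (1.54 and 1.18). Those of Ndufb10 (1.05 with -4.20) and Rpl13a (-0.26 with 1.71) did not. A candidate explanation of the calls near Bak1 and Bax is chromosome segments of another strain there. The strains' sequences were not used here. For H2-Eb1 and H2-Q7 near Bak1, and Snrpn and Ndn near Bax, variants and changed levels were not told apart either.

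The interferon-stimulated genes were higher in Casp9 KO by a median of 1.64. With the Xist level of each array as a covariate the median was 1.58 (camera adjusted p = 3.5e-93), which argues against donor sex as the whole cause. Admixed monocytes, macrophages or dendritic cells were assumed to raise their markers by about as much. The upper quartile of the 22 markers below 8 in WT experiment 1 was 0.76. The abundant Ly6c1, Lyz1, Ccl9, Lyz2 and F13a1 were at 0.43, 0.21, 0.58, 0.20 and 0.43, none past the test. The marker list did rise, with 32 of 34 members higher, 2 of them called, and a median of 0.55 (camera adjusted p = 9.0e-13). A smaller share of such cells is therefore not excluded, although a sort for Lineage-negative cells would remove most of them. The loss of caspase-9 may thus be the cause, as a hypothesis found and tested on the same data, while differences between the donors or recipients other than sex stay open and untested.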

How the results depend on the processing

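The Xist covariate and the authors' probe filter were added after the data and the main results had been seen, the covariate before its own result; the cause of the changes given here was not tested unless stated.

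Leaving out single arrays gave 87 to 667 genes for Casp9 KO, 97 to 468 for Bak/Bax DKO, 96 to 825 for the difference of effects and 326 to 2346 for the wild types. The highest came each time without Bak/Bax DKO replicate 2, whose residuals enter the shared variance. The correlation of the effects ranged from -0.025 to 0.040. It was -0.020 with the Xist covariate.

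Median-centred arrays gave 93 genes for Bak/Bax DKO, 162 for the difference and 351 for the wild types. There the Bak/Bax DKO medians of p53 targets and cell cycle genes turned to -0.012 and -0.26, and the difference for mitochondrial biogenesis genes to 0.056. Array weights gave 936, 571, 930 and 3207 genes for Casp9 KO, Bak/Bax DKO, the difference and the wild types. Only the 6 arrays of a comparison gave 589, 21 and 2727 for Casp9 KO, Bak/Bax DKO and the wild types. The Xist covariate gave 107, 147 and 163 for Casp9 KO, Bak/Bax DKO and the difference. Ordinary variances gave 143 for the difference, and all probes 1399 for the wild types, where more tests are made by construction.

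The replicate number as a block gave 109, 129 and 77 genes for Casp9 KO, Bak/Bax DKO and the difference. The labels do not say that numbers pair samples. Deviations of samples with the same number correlated at 0.24, -0.06 and 0.09 in experiment 1 and at 0.10, 0.06 and 0.04 in experiment 2, and not every sample correlated best with its own number.

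Without a detection filter the Casp9 KO median of endothelium and stroma genes was 0.023 and the list's call was lost (camera adjusted p = 0.879). Ftl1 in Bak/Bax DKO was at -0.68 with probes averaged, at -3.12 with the authors' filter and at -0.066 to 0.66 with single arrays left out. Where another probe became the brightest, by construction, Ndufb10 ranged from -4.53 to 1.06 in Bak/Bax DKO and from -1.02 to 4.47 in the difference, and was at 1.03 with only the 6 arrays. Snrpn ranged in the same way from -0.25 to 3.96 in Bak/Bax DKO and from -3.93 to 0.34 in the difference. The respiratory chain median in Bak/Bax DKO ranged from -0.14 to 0.012.

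With single arrays left out, 2426 values of named genes kept direction and side of the threshold, 242 lost the call, 68 gained one and 21 reversed; under the other alternatives these counts were 2840, 237, 98 and 3. For gene lists they were 798, 17, 12 and 1, and 798, 14, 12 and 4. The interferon-stimulated genes had a median of 1.51 to 1.66 in Casp9 KO with single arrays left out and 1.13 to 1.68 otherwise. With single arrays left out, the lists past camera numbered 12 to 14, 7 to 10 and 8 to 13 for Casp9 KO, Bak/Bax DKO and the difference. Under the other alternatives they numbered 12 to 13, 9 to 12 and 9 to 11. Signal over background limits genes near the detection limit.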

Other observations

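The genes named here were chosen after their values had been seen. Among the 41 genes that rose in both knockouts were Axl, a receptor kinase that binds apoptotic cells (1.43 in Casp9 KO and 1.44 in Bak/Bax DKO), the checkpoint receptor gene Lag3 (0.98 and 0.99) and the serine protease inhibitor genes Serpina3f (2.98 and 1.74) and Serpina3g (1.33 and 1.38). Nlrc5, which drives MHC class I genes, rose by 1.23 and 0.75. The RNA sensor genes Ddx58 (1.54 and 1.02) and Dhx58 (2.23 and 0.91) rose as well; both are counted among the interferon-stimulated genes and not among the cytosolic nucleic acid sensing genes.

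Xist was above 8 on the log2 scale on 2 of 3 WT experiment 1 arrays, 1 Casp9 KO array, 1 WT experiment 2 array and 0 Bak/Bax DKO arrays.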
